A study of Mus musculus with 7 samples.

How the data were processed

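Bone marrow-derived dendritic cells (BMDCs), antigen-presenting cells grown from mouse marrow in GM-CSF at 20 ng/ml and IL-4 at 10 ng/ml with part of the medium renewed on days 3 and 6, were the source of all 7 libraries, per the labels' protocols. The 6 chromatin immunoprecipitation (ChIP) libraries came from wild-type (WT) cells and from cells lacking RelB (RelBko), either before stimulation (0 h) or after 1 h with lipopolysaccharide (LPS) at 10 ng/mL, and the remaining library was input DNA of WT cells. RelB ChIP covered both genotypes at both times, RelA ChIP covered both genotypes at 1 h, and each group held 1 library. Per the labels, about 10 M cells per sample were fixed with DSG at 1.0 mM and PFA at 1.0%, sheared by sonication and made into libraries with a commercial kit. The treatment text names, beside LPS, a reagent whose name belongs to a CpG oligonucleotide; the stimulus is called LPS here, as in the sample labels. The labels give no time or treatment for the input.

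The deposited table holds, per the file headers, RPKM values (reads scaled by region length and library total), calculated by the authors for each of the 7 libraries over 93611 regions common to all of them. Another deposited file holds the coordinates of the same 93611 regions and no measurement. Other deposited columns give, per the labels and headers, the distance to a transcription start site (TSS) in bp, the nearest gene and a class of annotation. The submitters' processing notes name HISAT2, HOMER, bedtools and the mouse build mm9; the role of each tool, its version, and how the regions were chosen are not given in the sources used here. The regions were 168 to 1029 bp long (median 361 bp) and lay on 20 chromosomes, 11.0% of them in promoters, 44.1% in introns, 39.2% between genes and 5.69% in other classes. Coordinates are given in mm9, counted from 1.

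Within each library, every RPKM value multiplied by its region's length was a whole multiple of the smallest such product (100% of values within 0.01 read), so that reads per region and the library total behind the RPKM could be recovered. No value lay under that of 1 read in any library, although the input held few reads per region. In the input, 5623, 12409 and 15131 regions held 1, 2 and 3 reads. For scattered counts, the ratio of regions at successive read numbers, multiplied by the higher read number, rises steadily; it ran 4.41, 3.66 and 3.95 with the counts as recovered and 2.21, 2.44 and 2.96 with 1 read taken off each, so a read added to every count before scaling is possible. Read numbers are printed as recovered and may be 1 too high, which matters most where a value rests on 1 to 3 reads, and an alternative with 1 read taken off every value was run.

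All comparisons used log2 ratios of RPKM after adding a pseudocount of 0.5 RPKM, a scale that understates the change of weak regions. A region was enriched in a library at 2 RPKM or more and at 2-fold or more over the input with the same pseudocount. Regions enriched in at least 1 of the 2 libraries of a comparison were compared, and those differing by 2-fold or more were called higher or lower. Intervals of ratios of reads are exact (Clopper-Pearson) 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. With 1 library per group there is no replicate check of any difference between genotypes or times, and no p-value across regions is given. RelB-specific regions were those enriched in the WT RelB library at 1 h and at least 2-fold above the RelBko RelB library of that time. RelA-enriched regions were called against input alone, since a RelA library from cells without RelA and a RelA library at 0 h were not analysed here.

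There were 13 gene lists with 259 genes: NF-kB pathway and feedback genes, inflammatory cytokines and chemokines, interferon beta and interferon-stimulated genes, dendritic cell maturation genes, noncanonical NF-kB and lymphoid chemokine genes, immediate early genes, survival and stress genes, myeloid and dendritic cell lineage genes, housekeeping genes, and markers of neutrophils, of B cells, of T and NK cells, and of erythroid and mast cells. Older symbols were matched through a RefSeq gene table of a later mouse assembly (GRCm38), used for names only. Each gene was represented by the region assigned to it in the deposited annotation, within 100 kb of the TSS, with the highest mean RPKM of both libraries compared. Where a list had at least 5 measured members, its median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and a median outside the 2.5th to 97.5th percentile was called outside the random range. These percentiles describe the libraries and test nothing across conditions. In each comparison the genes named are taken from the 3 members of each list with the highest mean RPKM and, in each direction, from the 8 genes with the largest log2 ratio among compared regions within 100 kb of the TSS with at least 4 RPKM in the higher library. Other genes are said to have been chosen after their values were seen. The comparisons, thresholds, lists, naming rule and first set of alternatives were fixed before the data were examined.

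The recovered totals ran from 13188833 to 35064429 reads, and the interval of each library's share of reads in regions reached at most 0.0227 percentage points to either side. On simulated data with 200 regions changed by known folds among the 93611, all regions changed 8-fold were called in each of the 5 comparisons. Of regions changed 3-fold, the same steps called 94.1% in both comparisons of RelB between genotypes, 97.2% for RelB over time in WT, 80.0% for RelB over time in RelBko and 91.2% for RelA. Of unchanged regions, 0.683% were called in the simulated RelA comparison, and 4.07% in that of RelB over time in RelBko, whose values are the lowest. The simulated counts held counting error only, around the pooled rate of both libraries, and the changed regions were taken from enriched ones. Variation between libraries or cultures was not simulated, so these shares are not rates of false calls in the data.

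The alternatives were pseudocounts of 0.1 and 1 RPKM, no filter on low values, an RPKM minimum of 4, scaling to a median ratio of 1 over the compared regions, scaling on 3628 regions enriched in no library, a requirement that the counting interval exclude equality, a 4-fold limit for RelB-specific regions, and lists restricted to 10 kb of the TSS or averaged over all regions of a gene. Alternatives added after the data were seen were regions with under 5 RPKM in the input, regions over 10 Mb from the Relb gene, the RelBko value of the same time taken off, the RelBko library at 1 h as control for 0 h, RelA enrichment in either library, sparse signal bins left out and 1 read taken off every value. Scaling to a median ratio of 1 assumes that most regions do not differ, and the regions enriched in no library still hold some signal. Reads, peak calls per library and sequence motifs were not analysed here. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.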

Results

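RelA and RelB are DNA-binding subunits of the NF-kB family. RelA is the main subunit released within minutes by inflammatory signals such as LPS, and RelB is best known from the noncanonical NF-kB pathway and from dendritic cell maturation. The series asks how the loss of RelB affects the DNA binding of RelA. Binding was read from 7 ChIP-seq libraries of mouse BMDCs, with 1 library per group and RPKM values over 93611 regions in mm9. The WT RelB libraries held 35064429 reads at 0 h and 28425471 at 1 h, of which 38.4% and 42.4% fell in the regions. The WT RelA library at 1 h held 17590435 reads, with 37.9% in the regions. The RelBko RelB libraries held 17485035 and 19498468 reads, of which 7.41% and 4.62% fell in the regions, against 3.52% of 13188833 reads in the input. The RelBko RelA library held 23956299 reads, with 37.2% in the regions. Enriched over input were 71023 regions for RelB in WT at 0 h, 76450 at 1 h and 76741 for RelA in WT. In RelBko these numbers were 22528 and 5957 for RelB and 71083 for RelA.

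The gene removed in the RelBko cells, Relb, carried 5 regions on chromosome 7. At its promoter region (20214655 to 20215034, 57 bp from the TSS on the upstream side, distance -57), RelB signal was 104 RPKM at 0 h and 49.3 RPKM at 1 h in WT, and 11.9 and 4.18 RPKM in RelBko. RelA signal at the same promoter was 89.0 RPKM in WT (595 reads) and 70.6 RPKM in RelBko (643 reads), with 2.0 RPKM in the input. The Relb regions held DNA reads in every RelBko library, so these regions do not show the deletion itself and do not check the genotype label.

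RelB ChIP at 1 h was compared between WT and RelBko to find regions with more signal where the RelB gene is present. At the deposited scale nearly all were called: 73417 of 76583 compared regions (95.9%) were higher in WT and 98 were lower, with a median 5.52-fold difference (log2 2.47). The count depended on scaling, with 51995 higher when scaled on regions without enrichment and 10909 higher and 8251 lower with a median ratio of 1. With 1 library per genotype, dependence on the RelB gene was not separated from other differences between the libraries. The promoter of Nfkbia, which encodes the inhibitor that ends NF-kB activity (chromosome 12, 56593546 to 56593910), had 207 RPKM in WT and 9.84 RPKM in RelBko, a ratio of reads of 21.1 (95% interval 16.6 to 27.1). Near Ccr7, the receptor that guides dendritic cells to lymph nodes (chromosome 11, 99029327 to 99029711), RelB signal was 156 against 3.86 RPKM, a ratio of 40.4 (28.0 to 60.4). Near Il12b, which encodes a subunit of interleukin 12 (chromosome 11, 44195619 to 44196062), it was 135 against 4.97 RPKM, a ratio of 27.2 (20.1 to 37.7).

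Compared regions at 1 h entered almost only through the WT library, with 76450 enriched there and 5957 in RelBko. Each gene was taken at its region of highest mean signal, so high counts were near certain for any list. Every measured member of 11 of the 13 lists was higher in WT at 1 h. They included all 18 NF-kB pathway and feedback genes, with Traf1, a signalling adaptor, at 121 against 4.0 RPKM and Nfkbiz at 125 against 7.99 RPKM. All 29 inflammatory cytokine and chemokine genes were higher, among them Il1a at 142 against 6.86 RPKM and Cxcl16 at 138 against 5.80 RPKM. All 26 dendritic cell maturation genes were higher, with the surface proteins Cd83 at 161 against 5.14 RPKM and Cd40 at 133 against 6.37 RPKM. So were all 31 interferon genes (Usp18 at 69.2 against 2.93 RPKM) and all 10 noncanonical NF-kB genes (Nfkb2 at 82.0 against 7.22 RPKM). The same held for all 21 immediate early genes (Egr3 at 141 against 6.88 RPKM), all 18 survival and stress genes (Gadd45b at 97.0 against 5.41 RPKM) and all 22 myeloid and dendritic cell lineage genes (Irf8 at 119 against 4.70 RPKM). Genes outside the dendritic cell program were called too, with all 10 B cell, all 13 T and NK cell and all 19 housekeeping genes higher in WT. Their median log2 ratios were 2.77, 3.40 and 3.11, against 4.16 for maturation genes, each inside the range of random lists of like signal. With a median ratio of 1, 1, 4 and 5 of them stayed higher and 3 housekeeping genes were lower, against 17 of 26 maturation genes higher. Differences between lists were not tested. Actb had 92.5 against 3.86 RPKM. Camp was the exception among neutrophil genes and Epor among erythroid and mast cell genes, both chosen after their values were seen, with 10 of 11 and 5 of 6 higher. The list medians of NF-kB pathway genes (log2 3.89, random lists 3.96 to 4.51), cytokines (3.73, random 3.77 to 4.26) and noncanonical genes (3.49, random 3.51 to 4.30) lay below those of random lists of like signal. None of these 3 stayed outside the random range within 10 kb of the TSS or with all regions of a gene averaged.

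Among the largest differences, Cd63, a tetraspanin of endosomes, had 109 RPKM at its promoter in WT and 0.965 RPKM in RelBko (ratio 113, interval 51.9 to 309). An intron of Gcnt2 had 86.3 against 0.447 RPKM, the latter from 3 reads (ratio 193, 65.8 to 938). Serpinb1b, Hdac7, B930018H19Rik, Rasa2 and Otos were also in this group. Most regions lower in WT were weak, with a median of 3.97 RPKM in RelBko, and the largest such difference within 100 kb of a TSS, in an intron of Esco1, rested on 1 read in WT and 20 reads in RelBko. A region 269734 bp from the TSS of Fam172a, chosen after its values were seen, differed more, with 48.2 RPKM in WT and 2803 RPKM in RelBko, and had 78.5 RPKM in the input, the highest input value of all regions. Promoters made up 12.8% of the regions higher in WT (95% Wilson interval 12.5 to 13.0%) and 12.5% of those compared. Scaling to a median ratio of 1, which assumes that most regions do not differ between the genotypes and moves the log2 median by -2.47, left 10909 regions higher and 8251 lower, and the median of the housekeeping list at 0.29. Of 234 list entries it left 100 higher, with 9 of 18 NF-kB pathway genes and 6 of 31 interferon genes, and made 6 lower. Scaling on regions without enrichment moved the median by -1.03 and left 51995 regions higher and 156 lower, and 219 list entries higher.

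Before LPS, the same comparison at 0 h shows the RelB signal present in unstimulated BMDCs. RelB signal was higher in WT in 61621 of 71649 compared regions (86.0%) and lower in 361, with a median 3.61-fold difference (log2 1.85). Nfkbia had 328 RPKM in WT and 23.8 RPKM in RelBko, a ratio of 13.8 (11.7 to 16.3). The promoter of Traf3, an adaptor that restrains the noncanonical pathway, had 244 against 10.5 RPKM, a ratio of 23.3 (18.2 to 30.3), and Birc3, an inhibitor of apoptosis, had 196 against 11.1 RPKM, a ratio of 17.7 (13.9 to 22.7). Of the 73417 RelB-specific regions at 1 h, 57530 (78.4%) were also higher in WT at 0 h.

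All measured members were higher in WT at 0 h for NF-kB pathway genes (18, with Tnfaip3 at 161 against 10.6 RPKM), cytokines (29, with Cxcl16 at 234 against 12.3 RPKM and Il12b at 151 against 4.40 RPKM), dendritic cell maturation genes (26, with Ccr7 at 149 against 14.6 RPKM) and noncanonical genes (9). The same held for immediate early genes (21, with Egr3 at 191 against 9.56 RPKM), survival and stress genes (18), myeloid and dendritic cell lineage genes (22, with Spi1, which encodes the myeloid factor PU.1, at 148 against 7.50 RPKM), B cell genes (10) and T and NK cell genes (13). Of the interferon genes 28 of 31 were higher, with Socs1 at 109 against 3.47 RPKM, and Stat2, Ifit2 and Oas1a, chosen after their values were seen, stayed within 2-fold. Neutrophil genes were higher in 9 of 10 cases, erythroid and mast cell genes in 5 of 6 and housekeeping genes in 16 of 19. As at 1 h, most compared regions entered through WT (71023 enriched, 22528 in RelBko), so high counts were likely for any list. Immediate early genes had a median log2 of 2.57, below random lists of like signal (2.94 to 3.75), and housekeeping genes had a median of 1.93 (random 1.95 to 2.97). Within 10 kb of the TSS only the immediate early list stayed outside the random range, and neither did with all regions averaged.

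The largest differences at 0 h lay in introns of Dock9 (84.1 against 0.599 RPKM, the latter from 4 reads) and Txndc11 (81.5 against 0.915 RPKM) and near Actl6a (94.1 against 0.839 RPKM) and Pkdcc (116 against 1.17 RPKM), with Mir7676-2, Gcnt2, Gm12505 and Tmem39a behind them. In the other direction, a region near Mybpc3 had 1.22 RPKM in WT and 128 RPKM in RelBko (inverse ratio 105, 62.3 to 193), and no other library exceeded 2.55 RPKM there. Promoters were 11.2% of the regions higher in WT (11.0 to 11.5%) and 13.0% of those compared. Scaling to a median ratio of 1 moved the log2 median by -1.85, left 9902 regions higher and 7074 lower, and turned the median of the housekeeping list to -0.07 and that of the erythroid and mast cell list to -0.09. Of 232 list entries it left 87 higher, with 10 of 18 NF-kB pathway genes and 6 of 31 interferon genes, and made 8 lower. Scaling on regions without enrichment moved it by -0.79 and left 37821 higher and 692 lower, and 193 list entries higher, with 24 of 29 cytokine, 19 of 22 lineage and 7 of 10 B cell genes. With the RelBko library at 1 h as control, an added alternative, 104 were lower.

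**Figure D1:**
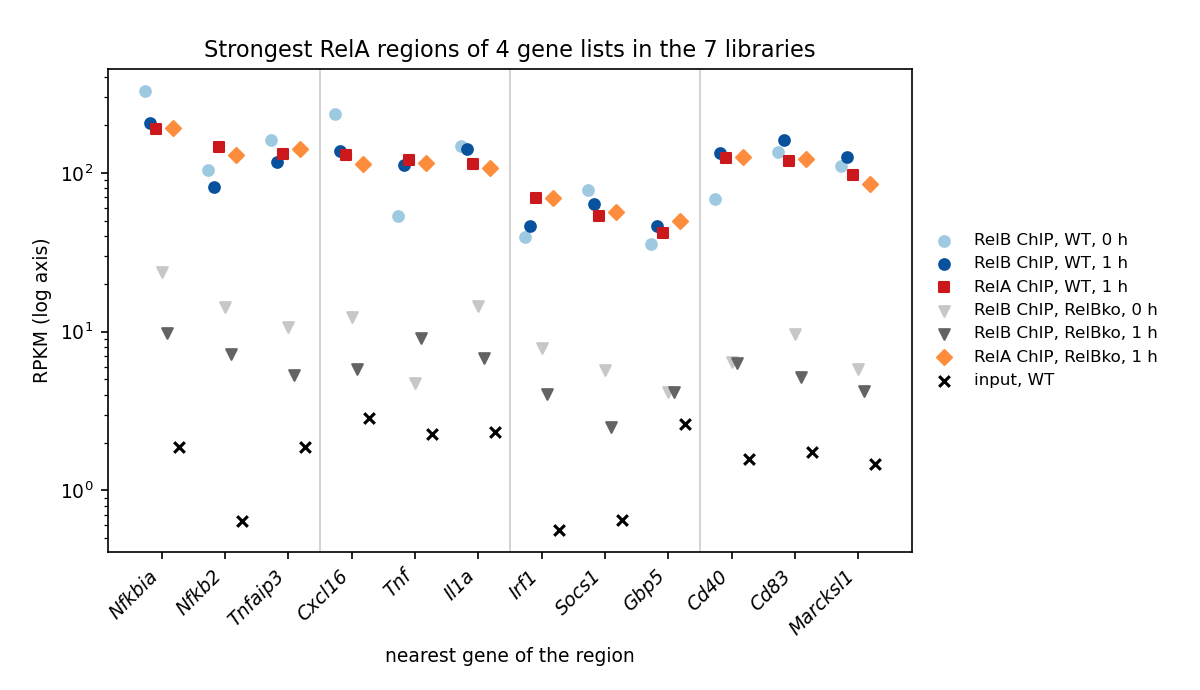
RPKM on a log axis for the RelB and RelA libraries and the input at the regions with the most RelA signal of NF-kB pathway, cytokine, interferon and dendritic cell maturation genes, with 1 point per library. At the Nfkbia promoter RelB signal was 207 RPKM in WT and 9.84 RPKM in RelBko at 1 h, while RelA signal was 190 and 191 RPKM.

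Between 0 h and 1 h of LPS, RelB signal in WT cells differed by 2-fold or more at a minority of regions. With 1 library per time, an effect of LPS was not separated from variation between libraries. Of 80966 compared regions, 8901 (11.0%) were higher at 1 h and 1358 (1.68%) lower, and the median log2 change was 0.14. The promoter of Dusp2, a phosphatase of MAP kinases, rose from 39.0 to 138 RPKM (log2 1.81), and a region near Tnfrsf13b, a receptor for B cell survival factors, rose from 31.7 to 72.0 RPKM (ratio 2.27, 1.89 to 2.73). The Traf3 promoter fell from 244 to 121 RPKM (ratio 0.497, 0.464 to 0.531) and a region near Spi1 fell from 148 to 72.7 RPKM (ratio 0.490, 0.449 to 0.534).

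NF-kB pathway and feedback genes had a median log2 change of -0.37, below random lists of like signal (-0.34 to 0.14), with 15 of 18 members below 0 and 1 called lower. Nfkbia had 328 RPKM at 0 h and 207 RPKM at 1 h (ratio 0.631, 0.599 to 0.665), Birc3 had 196 and 101 RPKM (ratio 0.514), and Tnfaip3 had 161 and 117 RPKM (ratio 0.725). The called member, Traf2, chosen after its values were seen, fell from 150 to 59.0 RPKM. Averaged over all regions of each gene, the median of this list was 0.03 and inside the random range. Inflammatory cytokines and chemokines had a median of 0.25, above random lists (-0.19 to 0.19), with 4 of 29 higher and none lower, although within 10 kb of the TSS the list was inside the random range. These 4, chosen after their values were seen, were Tnfsf9 from 18.1 to 66.7 RPKM, Il12a from 17.2 to 53.6 RPKM, Ebi3 from 35.6 to 101 RPKM and Csf2 from 9.77 to 20.3 RPKM.

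Interferon genes had a median of 0.27 (random -0.07 to 0.30), with Oas1a, Ifi205 and Isg15 higher among 31 and Socs1 lower (109 to 53.3 RPKM). Immediate early genes had a median of 0.17 (random -0.28 to 0.19) with Dusp2 higher among 21. Dendritic cell maturation genes had a median of 0.04, turning to -0.11 with a median ratio of 1, with Aldh1a2, an enzyme of retinoic acid synthesis, higher among 26 (12.7 to 37.7 RPKM), while Ccr7 had 149 and 156 RPKM and Cd83 had 135 and 161 RPKM. Noncanonical genes (median 0.07, turning to -0.08) had Tnfrsf13b higher and Traf3 lower among 10, and survival and stress genes (0.09, turning to -0.06) had Ptgs2 higher among 18. Among 22 myeloid and dendritic cell lineage genes (0.00, turning to -0.15), Mertk was higher, and Spi1 and Lyz1 were lower. Neutrophil genes (0.20) had Prtn3 and Mmp8 higher among 12, and B cell genes (0.00, turning to -0.14) had Fcer2a and Ebf1 higher among 11. T and NK cell genes (0.25) had Cd4 lower among 13 (66.2 to 22.3 RPKM). Erythroid and mast cell genes (0.43) had Ms4a2 higher and Gata1 lower among 7. None of 19 housekeeping genes was called (0.13, turning to -0.02). Those of these genes that are not among the 3 members of highest signal were chosen after their values were seen.

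Large rises were near Khdc1a (1.14 to 25 RPKM, ratio 21.9, 12.8 to 40.7) and in introns of Mtmr12 (0.588 to 16.3 RPKM), Pvr, an adhesion receptor (1.27 to 22.5 RPKM), and Rora, a nuclear receptor (0.908 to 14.2 RPKM), with Eea1, Pdss1, 4933427D06Rik and Mir582 beside them. Among the largest falls from 4 RPKM or more were those near Dock9 (4.81 to 0.228 RPKM, the latter from 2 reads, ratio 0.0474, 0.00560 to 0.180) and Nr3c1, the glucocorticoid receptor gene (6.33 to 1.38 RPKM, ratio 0.219, 0.114 to 0.389), with Ano2, Cbx7, Mbnl1, Gm13710, Blcap and Apoa4 beside them. Regions that rose were rarely promoters (4.65%, 4.23 to 5.11%), as were those that fell (2.65%, 1.92 to 3.65%), against 12.0% of those compared. Scaling to a median ratio of 1 moved the log2 median by -0.14 and gave 6932 higher and 2453 lower regions. It ended the calls of Csf2, Isg15, Ptgs2, Mmp8 and Ms4a2 and added Birc3, Cyld, Il10, Pdcd1lg2, Mmp9 and Cr2 as lower. Scaling on regions without enrichment moved the log2 median by -0.08 to 0.06 and gave 7600 higher and 1954 lower regions. Taking off the RelBko signal of the same time, an added alternative, gave 17066 higher and 2719 lower regions.

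In RelBko cells RelB ChIP gave weaker signal after 1 h of LPS than before it, a comparison of what the ChIP yields without the RelB gene. Of 23402 compared regions, 10315 (44.1%) were lower at 1 h and 202 higher, with a median log2 change of -0.93. Most of these regions entered through the 0 h library (22528 enriched, against 5957 at 1 h), which by itself favours falls at weak regions. Without the filter on low values the median was -0.43, with 16922 lower and 1490 higher of 93611 regions. Nfkbia fell from 23.8 to 9.84 RPKM (ratio 0.413, 0.307 to 0.552) and the Ccr7 region from 14.6 to 3.86 RPKM (ratio 0.265, 0.169 to 0.405). Housekeeping genes fell as well, in 7 of 12 cases (median -1.12, and -0.12 with a median ratio of 1), among them Pgk1, a glycolytic enzyme gene, from 9.69 to 3.19 RPKM.

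With a median ratio of 1 the median of NF-kB pathway genes, 9 of 18 lower, turned from -1.02 to 0.02, that of interferon genes, 5 of 22 lower, from -0.73 to 0.18, and that of dendritic cell maturation genes, 11 of 26 lower, from -0.90 to 0.13. It turned likewise for noncanonical genes (2 of 9 lower, -0.83 to 0.17), immediate early genes (10 of 21 lower, -0.97 to 0.01, with Ier3 at 15.2 and 5.25 RPKM), survival and stress genes (7 of 16 lower, -0.87 to 0.11) and myeloid and dendritic cell lineage genes (9 of 20 lower, -0.97 to 0.02, with Zbtb46 at 14.5 and 3.92 RPKM). It stayed below 0 for neutrophil genes (3 of 6 lower, -0.91), B cell genes (2 of 5 lower, -0.92) and T and NK cell genes (5 of 8 lower, -1.25), and erythroid and mast cell genes (2 of 4 lower, -1.12) were too few for random lists. The only list member called higher was Nos2, from 1.02 to 3.66 RPKM, chosen after its values were seen. The median of the cytokine list, -0.73 with 6 of 26 lower, lay above random lists of like signal (-1.21 to -0.81), and it did so within 10 kb of the TSS, with all regions averaged and with a median ratio of 1, where it was 0.25. The largest fall was near Mybpc3 (128 to 1.09 RPKM), followed by 0610040F04Rik, the promoter of Slc15a3, a peptide transporter gene (13.5 to 0.905 RPKM, from 40 and 3 reads, ratio 0.0673, 0.0133 to 0.211), Zfp36l2, Ndufb7, Tmem115, Arhgap27 and Chn2. The largest rises within 100 kb of a TSS, at Esco1, Ice1, Cyp2j12, H2-M10.3, Uchl4, Gm35986, Chrm2 and Ctla4, started from 1 or 2 reads, and farther from a TSS the Fam172a region rose from 89.2 to 2803 RPKM. Promoters were 26.8% of the lower regions (25.9 to 27.6%) and 23.2% of those compared. Scaling to a median ratio of 1 moved the log2 median by 0.93 and left 912 lower and 1261 higher regions, and 5 lower and 7 higher among 193 list entries, and scaling on regions without enrichment moved it by 0.20 and left 6856 lower and 330 higher, and 54 list entries lower and 2 higher, with 1 lower and 1 higher among the 26 cytokine genes.

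RelA and RelB signal coincided in WT cells at 1 h. Of the 73417 RelB-specific regions, 66257 (90.2%, exact interval 90.0 to 90.5%) were also RelA-enriched, against 10484 of the 20194 other regions (51.9%). Both shares moved with the settings, to 78.2% and 23.4% with scaling on regions without enrichment, 87.5% and 18.7% with a minimum of 4 RPKM and 98.7% and 78.8% with a median ratio of 1. Conversely, 86.3% of RelA-enriched regions were RelB-specific. Where RelB signal reached 20 RPKM, 16264 of 16266 regions were RelA-enriched. The Nfkbia promoter carried 207 RPKM of RelB and 190 RPKM of RelA, and the Cd40 promoter carried 133 and 124 RPKM. Across regions, which are not independent replicates, log RPKM of RelB and RelA correlated with Pearson r 0.88 and Spearman rho 0.88. Part of this is shared by libraries without RelB. WT RelA correlated with RelBko RelB at Pearson r 0.73 (0 h) and 0.68 (1 h) and with the input at 0.45. The regions are a common set chosen in a way not given, and 82.0% of all of them were RelA-enriched in WT.

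Loss of RelB left RelA signal at the strongest regions of NF-kB target genes close to its WT level after 1 h of LPS. This is the comparison the series is named for. At the Nfkbia promoter RelA signal was 191 RPKM in RelBko and 190 RPKM in WT (ratio 1.01, 0.936 to 1.09), and at the promoter of Tnf, which encodes a central inflammatory cytokine, it was 116 and 120 RPKM (ratio 0.966, 0.840 to 1.11). The Cd40 promoter had 126 and 124 RPKM (ratio 1.02, 0.925 to 1.12) and the promoter of the interferon regulator Irf1 had 69.7 and 69.2 RPKM (ratio 1.01, 0.895 to 1.13). Across 80885 compared regions, 75836 (93.8%) differed by less than 2-fold, 1055 (1.30%) were higher in RelBko and 3994 (4.94%) were lower, and the median log2 ratio was -0.06 (interval of the median -0.06 to -0.05). Of the regions RelA-enriched in WT, 66939 (87.2%) were also enriched in RelBko, and RelA signal in both genotypes correlated across regions with Pearson r 0.94 and Spearman rho 0.93.

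Each gene was taken at its region of highest mean RelA signal, and strong regions were rarely called. From 16 to 32 RPKM of mean RelA signal, 99.3% of 12468 regions were within 2-fold. Weaker regions of the same genes could differ, such as an intron region of Relb, chosen after its values were seen. It had 5.85 RPKM in RelBko (46 reads) and 1.91 RPKM in WT (11 reads). At the regions taken, no member was called in 11 of the 13 lists. None of 18 NF-kB pathway genes was (median log2 -0.00, and 0.06 with a median ratio of 1), with Nfkb2 at 130 RPKM in RelBko against 145 RPKM in WT and Tnfaip3 at 141 against 131 RPKM. None of 29 cytokine genes was (-0.04, and 0.02 with that scaling), with Cxcl16 at 114 against 130 RPKM and Il1a at 108 against 114 RPKM. The same held for 32 interferon genes (0.02), with Gbp5, a guanylate-binding protein gene, at 49.9 against 41.6 RPKM, for 26 dendritic cell maturation genes (0.06), with Cd83 at 122 against 119 RPKM, and for 11 noncanonical genes (0.02), with Tnfrsf13b at 73.8 against 52.8 RPKM (ratio 1.40, 1.15 to 1.71). It held for 21 immediate early genes (-0.00, and 0.06 with that scaling), with Dusp2 at 134 against 121 RPKM, for 18 survival and stress genes (0.04), with Bcl2l1 at 115 against 112 RPKM, and for 22 myeloid and dendritic cell lineage genes (-0.02, and 0.04 with that scaling), with Flt3 at 77.7 against 71.2 RPKM. Neutrophil genes (14, median -0.18), B cell genes (12, 0.01) and erythroid and mast cell genes (6, -0.22) held no called member either, with Gata2 at 18.2 against 9.71 RPKM (ratio 1.88, 1.37 to 2.60). T and NK cell genes had a median of -0.21, below random lists (-0.19 to 0.20), with Lck lower among 14 (0.605 against 2.47 RPKM), but the list lay inside the random range within 10 kb of the TSS and with all regions averaged. Of 19 housekeeping genes (0.09), Pgk1 was higher at its promoter (chromosome X, 103382065 to 103382418, 44.0 against 14.9 RPKM), and both called genes were chosen after their values were seen.

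The called RelA differences lay mostly at weak regions. Regions lower in RelBko had a median of 1.36 RPKM in RelBko and 4.20 RPKM in WT, those higher had 4.45 and 1.56 RPKM, and 90 lower and 49 higher regions reached 20 RPKM in the higher library. At a mean RelA signal under 2 RPKM, 25.2% of 4246 regions were lower and 6.15% higher, whereas from 64 RPKM up 99.9% of 980 regions were within 2-fold. Near Dmbt1 RelA signal was 0.988 RPKM in RelBko and 17.8 RPKM in WT (inverse ratio 18.0, 8.83 to 42.9), near Meis3, a homeobox gene, 1.74 and 25.6 RPKM (14.7, 8.66 to 26.9), and at Rps6, a ribosomal protein gene, 1.33 and 21.4 RPKM (16.1, 8.44 to 34.4). Abhd2, Plekhm1, Cdc14a and 2410089E03Rik were lower too, and at Zc3h13, with 0.248 and 56.5 RPKM, no library other than WT RelA exceeded 3.97 RPKM. In the other direction, Opa3, a mitochondrial protein gene, had 14.5 against 0.693 RPKM (ratio 20.9, 7.95 to 78.1), Crxos 13.7 against 1.85 RPKM (7.40, 4.26 to 13.9) and an intron assigned to Pdcd4 13.1 against 0.347 RPKM, the latter from 2 reads (37.8, 10.2 to 316), with Mir455, Defb43, Tescl and Zfp229 beside them. Of these, Meis3, Opa3, Crxos and Tescl lie within 5 Mb of Relb, where 17.8% of 292 regions were called. DNA of another strain linked to the RelBko allele may contribute there and cannot be told apart from loss of RelB. Promoters were 2.43% of the lower regions (1.99 to 2.95%) and 4.36% of the higher (3.28 to 5.77%), against 12.4% of those compared. Scaling on regions without enrichment moved the log2 median by 0.12 to 0.06 and gave 1613 higher and 3035 lower regions.

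**Figure D2:**
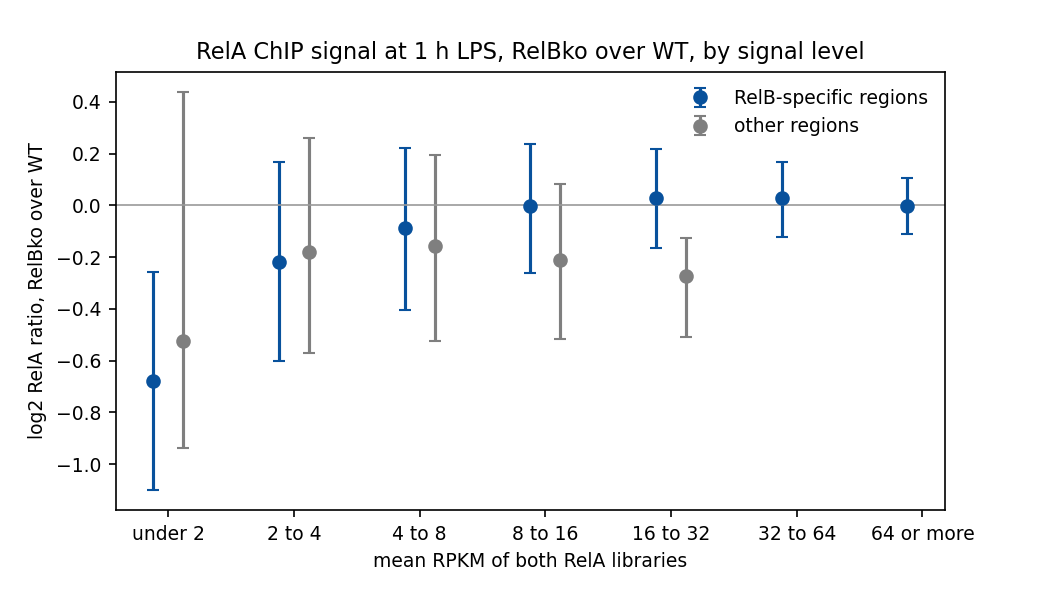
Log2 ratio of RelA signal in RelBko over WT at 1 h by range of mean RelA signal (RPKM), with points for medians and bars for quartiles of RelB-specific and other regions, ranges of under 20 regions left out. Among RelB-specific regions the median ran from -0.68 under 2 RPKM to 0.03 between 32 and 64 RPKM. Regions under 2 RPKM entered only with 1 library at 2 RPKM or more and the other below 2 RPKM.

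Taken over all levels of signal, RelA changed less at RelB-specific regions than at other RelA-enriched regions, but not at weak regions. The result depended on the scaling, which also changed which regions counted as RelB-specific. The median log2 ratio of RelBko over WT was -0.05 over 66257 RelB-specific regions and -0.37 over 10484 others, a difference of 0.31. The RelB-specific regions were stronger, with a median RelA signal of 9.08 against 2.93 RPKM, but their median also lay above that of random sets of the other regions matched on RelA signal (-0.23 to -0.21). This did not hold at weak regions: under 2 RPKM of mean RelA signal the median of compared regions was -0.68 in RelB-specific and -0.53 in other regions (30.3% and 21.7% lower), and between 2 and 4 RPKM it was -0.22 and -0.18. Of the 20 bins used for matching the weakest had -0.78 and -0.72, and the strongest held only 6 other regions for 3831 RelB-specific ones. The random sets drew other regions with replacement. Few strong regions were thus repeated many times, and the range of the random sets is too narrow to measure uncertainty. With bins of under 20 other regions left out, an added alternative, the RelB-specific median of -0.09 still lay above the random sets (-0.25 to -0.24). A bin kept there still held only 22 other regions for 3815 RelB-specific ones. Named regions such as the promoters of Nfkbia and Cd40, both RelB-specific, had RelA ratios of 1.01 and 1.02. Regions were taken by their RelA enrichment in WT, which by itself pulls weak regions down in RelBko, and the difference was 0.18 with enrichment in either library, an added alternative, and 0.12 without the filter on low values. With a median ratio of 1, 10763 regions counted as RelB-specific against 65173 others. The difference turned to -0.04, and the RelB-specific median, -0.06, lay below the random sets (0.09 to 0.10). With scaling on regions without enrichment, 40650 counted as RelB-specific against 9733 others. The difference stayed above 0 at 0.10, with a RelB-specific median of 0.08 narrowly below the random sets (0.09 to 0.10). Both scalings moved regions between the sets, so these values do not compare the same regions as before. With a 4-fold limit for RelB-specific regions the difference was 0.15 and the median, -0.04, lay inside the random sets (-0.05 to -0.04).

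**Figure D3:**
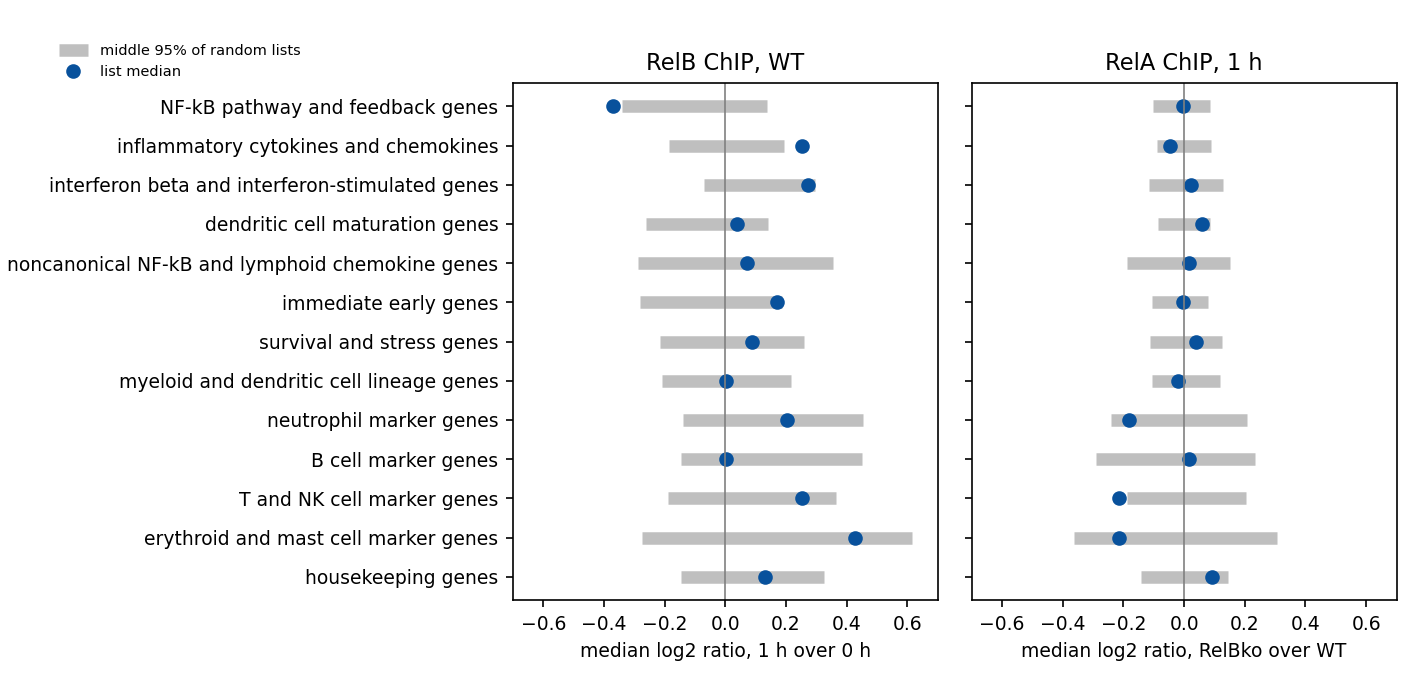
Median log2 ratio of each of the 13 gene lists (points) for RelB in WT, 1 h over 0 h, and for RelA at 1 h, RelBko over WT, with the middle 95% of random lists of the same size and like signal as bars. NF-kB pathway genes lay at -0.37 (-0.52 with a median ratio of 1) in the former and at -0.00 (0.06 with that scaling) in the latter.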

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

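Of the tests in this part, that of sequencing depth was written before its result was seen, and those of a constant share of RelB signal and of promoters against other regions were chosen only after. RelB signal after 1 h of LPS moved in opposite directions in the genotypes, with a median log2 change of 0.14 in WT over 80966 compared regions and -0.93 in RelBko over 23402, and -0.47 in RelBko over the regions compared in WT. The difference between both changes was not tested, since each group held 1 library. With a median ratio of 1 the medians of WT and of RelBko over their own compared regions are 0 by construction. With scaling on regions without enrichment they were 0.06 in WT and -0.73 in RelBko.

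The RelBko signal was higher before LPS, as at Nfkbia (23.8 and 9.84 RPKM), and 3 explanations were weighed. Sequencing depth is argued against, since the weaker 1 h library was the deeper one, with 19498468 against 17485035 reads. Thinning both to the smaller total left the 0 h library as it was, with 22528 enriched regions, and gave 6256 at 1 h. The thinning therefore adds little to the totals themselves. RelB protein or WT reads at a constant share of WT signal are argued against only as the whole signal of the 0 h library. Regions were sorted into eighths by RelA relative to RelB. The share of WT signal kept rose from 3.16% in the lowest eighth to 14.4% (4.55 times) in the highest. Promoters also became more frequent along the eighths. The share kept and the sorting both divide by RelB signal, so other signal added to a constant share could give such a rise too. Whether a constant share contributed beside other signal cannot be decided by this test. Open chromatin or other Rel proteins taken up by the antibody may contribute and cannot be told apart here: RelBko kept a median 14.1% of the WT signal in promoters and 7.65% elsewhere at 0 h, and 4.02% and 2.56% at 1 h, which shows where signal stayed at both times and not why it fell. A biological difference between stimulated and unstimulated RelBko cells stays open as untested. So does a difference between the libraries unrelated to LPS, since each time had 1 library, with 7.41% of reads in the regions at 0 h and 4.62% at 1 h.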

How the results depend on the processing

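Tests added after the data were seen were those with the RelBko value taken off, the RelBko library at 1 h as control, input under 5 RPKM, regions over 10 Mb from Relb, RelA enrichment in either library, sparse bins left out and 1 read taken off every value. Of 139 alternatives for the main results, 56 planned and 30 added ones stayed within 1.5 times or inside the interval, 45 planned and 5 added ones moved, 2 passed to the other side of the random sets and 1 no longer lay outside them; where no cause is named, the cause was not tested. With a median ratio of 1, RelB regions higher and lower in WT went to 10909 and 8251 at 1 h and 9902 and 7074 at 0 h, regions lower after LPS to 2453 in WT, and in RelBko to 912 lower and 1261 higher; the higher share of called regions went from 99.9% to 56.9%, 99.4% to 58.3%, 86.8% to 73.9% and 1.92% to 58.0%. With scaling on regions without enrichment, 156 were lower at 1 h, 37821 higher and 692 lower at 0 h, 330 higher and 6856 lower over time in RelBko, and 1613 higher for RelA, whose higher share of called regions went from 20.9% to 34.7%. By construction, a stricter minimum of 4 RPKM left fewer regions: 40 lower at 1 h, 162 lower at 0 h, 863 lower after LPS in WT, 60 higher and 6462 lower in RelBko, and 601 higher and 2142 lower for RelA. Without the filter 277 were lower at 1 h, 824 at 0 h, and 1490 higher and 16922 lower over time in RelBko. A pseudocount of 0.1 gave 2112 lower after LPS in WT, 368 higher in RelBko and 1658 higher for RelA, and a pseudocount of 1 gave 775 lower in WT, 113 higher and 6547 lower in RelBko, and 591 higher and 2407 lower for RelA. The RelBko library at 1 h as control left 104 lower at 0 h, and taking off the RelBko value gave 17066 higher and 2719 lower after LPS in WT.

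RelA-enriched regions 1h numbered 50383 with scaling on regions without enrichment. The RelA-enriched share of RelB-specific regions 1h was 90.7% with a pseudocount of 0.1, 89.8% with 1, 87.5% with a minimum of 4 RPKM (others 18.7%), 98.7% with a median ratio of 1 (others 78.8%), 78.2% with scaling on regions without enrichment (others 23.4%) and 89.8% with 1 read taken off (others 49.7%).

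The RelA median log2 ratio of RelBko over WT was -0.062 with a pseudocount of 0.1, -0.050 with 1, -0.069 without the filter, -0.029 with a minimum of 4 RPKM, 0 with a median ratio of 1, 0.059 with scaling on regions without enrichment and -0.049 with 1 read taken off. The RelA difference between RelB-specific and other regions was -0.042 with a median ratio of 1, 0.095 with scaling on regions without enrichment and 0.15 with the 4-fold limit. The median of RelB-specific regions fell from above to below the random sets with either scaling and lay inside them with that limit. All 3 settings also changed which regions counted as RelB-specific. Of 1092 alternatives for named regions 820 kept their value within the interval, of 86 for promoter shares 64 did, and of 191 for gene lists 167 stayed on their side of the random range, 11 moved outside and 13 inside. Some called regions rested on 1 to 3 reads in the lower library, such as Esco1 in WT at 1 h, and the effect of depth by read number was not tested. No paired analysis was possible because each group held 1 library.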

Other observations

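The comparison of RelA with RelB in WT cells, and all tests in this part except that of a subtracted RelB share and that of DNA copies, were chosen only after the results were seen. At 1 h in WT, 6336 of 85014 regions (7.45%) had RelA signal at least 2-fold above RelB and 6129 (7.21%) the reverse, with a median log2 ratio of -0.16; the antibodies differ, so levels compare only relative to other regions. NF-kB pathway genes had a median of 0.10, above random lists of like signal (-0.55 to -0.02). Of 14 neutrophil genes 5 had more RelA, among them Lcn2 (12.4 against 1.49 RPKM) and Camp (15.2 against 2.92 RPKM), and Retnlg had more RelB. Of 26 dendritic cell maturation genes 3 had more RelB: Ccr7 (156 against 62.0 RPKM), Cd200 (92.9 against 36.8 RPKM) and Cd274 (57.9 against 26.7 RPKM), as had Tnfsf11 (50.4 against 14.7 RPKM). Cxcl2 and Sod2 had more RelA (57.9 against 27.3 RPKM and 64.9 against 26.3 RPKM); these list members were chosen after their values were seen. Promoters were 1.81% of regions with more RelB (1.51 to 2.18%), 11.2% of those with more RelA and 11.8% of those compared. Large differences were seen near Gm20219 (RelA 32.8, RelB 0.673 RPKM, ratio 48.7, 23.2 to 123), and Ergic1 (RelB 27.6, RelA 3.95 RPKM, inverse ratio 6.97, 4.66 to 10.9).

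RelB-specific regions at 1 h were assigned to 16679 genes, with a median of 3 per gene and 20 or more for 171 genes. Foxp1 had 58, Creb5 49, Pde4b 47, Dock10 40 and Cd44, an adhesion receptor gene, 31. Of all 93611 regions 78.4% were RelB-specific, so these counts may mainly follow how many regions were assigned to each gene, which was not examined. Single regions stood out in 1 library: Zc3h13 in WT RelA (56.5 RPKM, at most 3.97 elsewhere) and Mybpc3 in RelBko RelB at 0 h (128 RPKM, at most 2.55). The highest value of any library was that of a region assigned to Fam172a in RelBko RelB at 1 h (2803 RPKM), with 555 RPKM in RelBko RelA, 238 RPKM in WT RelA and 78.5 RPKM in the input.

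RelA fell in RelBko at a share of the regions where RelB exceeded RelA. Of 1342 regions with RelB at 20 RPKM or more and at least 2-fold above RelA in WT, 263 (19.6%, Wilson interval 17.6 to 21.8%) were lower in RelA and 3 higher, such as Nfatc2 (15.4 to 1.40 RPKM), Gcnt2 (26.8 to 4.0 RPKM) and Rasa2 (33.8 to 4.41 RPKM), and the share reached 79.4% of the 34 regions with RelB over 4 times RelA; these examples were chosen after their values were seen. A difference in level between the RelA libraries is argued against, since random sets matched on RelA signal reached at most 2.31%. For WT RelB reads counted in the WT RelA library, taking off 25.8% of RelB left 17 of 263 regions lower, which decided nothing under bounds set beforehand. A second test, added afterwards, concerned a constant share, from such reads or from a RelA antibody that binds RelB alike everywhere. It took the median log2 RelA ratio at 4760 strong regions with RelB moderately above RelA (log2 0.5 to 1). Minus that at 638 with RelB below RelA (log2 -1 to -0.5), this was 0.056. The 23.9% share that the 263 regions needed would give -0.47, so the test argues against a constant share of that size. These regions were chosen for their fall, so that share may be too high, and a smaller one, which would give a smaller difference, was not tested. The test also takes RelA as otherwise unchanged in RelBko. For the antibody this test replaced an earlier count of strong RelB regions without RelA enrichment (107 in RelBko, 2 in WT), which a fall of RelA gives under any cause. Binding of RelB by the RelA antibody that varies among regions was not tested, and dependence of RelA on RelB at these regions stays open as untested.

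RelA differences were frequent within 10 Mb of Relb, where 20 regions were higher and 55 lower of 656 (11.4%, 9.22 to 14.1%), against 5.48% on the rest of chromosome 7, with Opa3, Igsf23 (16.6 to 1.55 RPKM), Pvr (22.1 to 3.99 RPKM) and the Apoe promoter (4.48 to 0.531 RPKM) as examples chosen after their values were seen. Against 36.7 regions expected from RelA signal the ratio was 2.04 (1.61 to 2.56), and the highest of 1139 windows of that width on other chromosomes was 1.88, so chance cannot be told apart; this test replaced an earlier one against matched sets (at most 8.99%), and the width was chosen after. A gain or loss of DNA copies across the whole window is argued against by a log2 shift of 0.068 in RelBko RelB reads over WT input of uncalled regions. That test left out the called regions, so gains or losses confined to them were not tested. DNA of another strain linked to the RelBko allele may contribute and cannot be told apart, since it would go with the genotype and the labels give C57BL/6 for all libraries without the origin of the allele. The called share was 17.8% of 292 regions within 5 Mb, 6.32% of 364 at 5 to 10 Mb, 7.43% of 202 at 10 to 15 Mb and 4.85% of 268 at 15 to 20 Mb, so it did not fall steadily beyond 5 Mb. This test replaced one on direction (26.7% of called regions higher), which decided nothing, since called regions went both ways everywhere (20.9% higher), and an effect of RelB itself stays open as untested.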
